A study of Homo sapiens with 24 samples.

How the data were processed

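Total RNA of THP-1 cells was reverse-transcribed and equal concentrations of cDNA were loaded on real-time PCR arrays with SYBR green chemistry, per the labels' protocols. Per the file headers, the plates were run for 40 cycles and a dissociation step on an Applied Biosystems instrument with SDS 1.4. Each of the 24 deposited plates lists 96 wells with a Ct (or the word undetermined) and a melting temperature (Tm) in °C, as the instrument's software gave them per the file headers. These values carry no normalization. The reaction volume in the headers is 25 µL, and 50 µL on 1 plate, media 12 hr A. How the authors scaled or tested the values is not given in the sources used here. The header named the treatment and time of the labels on 24 of 24 plates.

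The 84 wells of rows A to G were taken as the 84 panel assays. The files name no gene for a well, and no layout was assumed for these rows, so that the gene lists fixed in advance and their set tests were not run, and the genes fixed by name are not reported. For row H, wells H1 to H5 were taken as the panel's 5 reference wells from their usual place on such plates, which is an assumption. Each had a Ct under 35 on all 24 plates, with a mean of 15.4 to 20.8, and they were among the 9 wells of 96 with the smallest SD over plates. H6, in the usual place of a genomic DNA control, had a Ct under 35 on 8 plates. H7 (mean Ct 20.6), H8 (32.8) and H9 (21.5), where a reverse transcription control would usually stand in triplicate, disagreed with each other, and so did H10 (31.5) and H12 (16.2), so that no such control was computed. On the plate of a2NTD 6 hr A, well H11 read 37.1.

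Undetermined wells (63 in all) and Ct over 35 were set to 35. Of 2016 panel readings, 157 were at or over 35 or undetermined. Expression was computed as minus the Ct after subtracting the mean Ct of H1 to H5, a log2 scale that assumes doubling per cycle. Values at 35 are ceilings, which understate a difference between groups. No well had a Ct under 35 in all 3 libraries of one group and in none of the other at any time.

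Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in a single model of 24 libraries and 8 groups without a block. Benjamini-Hochberg adjustment ran over wells with a Ct under 35 in at least 3 of the 6 libraries of a time, 12 of the 24 for the average and the interaction, and 6 of the 12 media libraries for the media time course, with a threshold of 0.05. The design, these filters and most alternatives were set before the data were examined. The rule for named genes asked for the up to 15 largest rises and 8 largest falls per time, but since wells have no gene names, at most 2 wells that rose and 2 that fell are named, by size of change (by F test p in the media time course). The p-values measure the spread between libraries of a group in 1 cell line, pooled over the 8 groups. That spread mixes culture and PCR batch, and the labels do not say that letters A to C are the 3 occasions. With 3 libraries against 3, groups fail to overlap by chance in 10% of wells, and they did so in 9 of 76 wells at 2 hr, 32 of 79 at 6 hr, 28 of 77 at 12 hr and 35 of 79 at 24 hr.

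Letters A to C are shared by all groups. Deviations from group means over 69 wells correlated between the media and a2NTD libraries of a letter by more than 0.1 in 11 of 12 pairs, with a range of 0.04 to 0.70. The exception was letter A at 2 hr, whose a2NTD library is 1 of the 2 that stood apart. Letters B and C at 2 hr gave 0.22 and 0.23, and letter B at 12 hr gave 0.16. The letters were taken to pair libraries at 6, 12 and 24 hr, from the data and the shared run days. They were not taken to do so at 2 hr, which rests on letter A alone. Comparisons by letter at 2 hr use the letters as labelled.

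On simulated data with the spread of each well, 24 changed wells per run and 100 runs, the model called 39.5% of 2-fold, 78.1% of 4-fold and 93.3% of 8-fold changes among 79 wells at 6 hr, with 3.71% of calls false. At 2 hr, with 76 wells, the shares were 40.1, 78.6 and 92.4%. For the average over times they were 78.9, 98.0 and 99.8% among 76 wells. The simulated errors were normal and independent, with the same spread in both treatments, no effect of letter and no Ct ceiling. Rises and falls were pooled. The shares thus hold for data that meet the model's assumptions, and the power for falls near the ceiling was not simulated.

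Alternatives were other references (each of H1 to H5 alone, the median Ct of panel wells detected on all plates, none), ceilings of 32, 38 and 40, other detection filters, separate fits per time, robust and trended priors (statmod 1.5.0), replicate blocks, each library and each letter left out, plates with H6 under 35 left out, and other thresholds. The overlap of lists was also computed with a separate fit per time, under other references and without 2 libraries. Chosen after seeing the data were 4 of the 5 reference wells, centring on the median deviation, wells of row H tested too, a Tm within 1 °C of the well's median, and leaving out the libraries labelled a2NTD 2 hr A and a2NTD 12 hr A.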

Results

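The series measured transcripts of inflammatory and autoimmune genes in THP-1 cells, a human monocytic leukemia line, cultured in media alone or with a2NTD at 0.1 µg/ml. The a2NTD protein is the N-terminal domain of the a2 isoform of the vacuolar proton pump. Cells were taken at 2, 6, 12 and 24 hr, which gave 8 groups of 3 libraries, with replicates lettered A, B and C, and per the labels' protocols the experiment was done on 3 separate occasions. Each library was run on a 96-well PCR array whose panel holds assays of 84 genes. The wells are given here by plate position, since the files pair no gene name with a well, so that the wells below cannot be read as named genes and no gene group was tested. At most 2 wells that rose and 2 that fell are named per comparison by the fixed rule, and any other well is said to have been chosen after its values were seen.

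Between 75 and 83 of the 84 panel wells had a threshold cycle (Ct) under 35 on each plate, and 69 had one on all 24 plates. The mean Ct of wells H1 to H5, taken as the reference wells, lay between 16.9 and 18.1 on every plate, with an SD of 0.250 over the 24 plates. Averaged over the 4 times, the Ct of these 5 wells differed between a2NTD and media by -0.27 ± 0.13 (SE) in H1, -0.06 in H2, 0.01 in H3, -0.02 in H4 and -0.16 in H5, and none of these differences passed limma's test (lowest adjusted p = 0.207). By time, the differences in these wells ran from -0.30 to -0.04 at 2 hr and from -0.20 to 0.04 at 6 hr. They ran from -0.45 to -0.04 at 12 hr and from -0.16 to 0.31 at 24 hr, and were not tested by time. Expression is given as log2 relative to the mean of these wells, so that a difference of 1 is a 2-fold difference in template.

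Replicates of a group lay at a median root mean square distance of 0.714 log2 units from the mean of the other libraries of their group, over the 69 wells detected on every plate, with a range of 0.340 to 1.28 in 22 of the 24 libraries. The 1.28 was that of a2NTD 6 hr A and includes 1 aberrant reading, in well G11. Its Ct there was 32.7 with a melting temperature of 70 °C, against 23.4 (83.7 °C) in library B and 23.1 (83.6 °C) in library C. The distance without this well was not computed. The remaining 2 libraries stood apart. The library labelled a2NTD 2 hr A lay 1.71 from the other 2 libraries of its group and 0.609 from the other 2 of a2NTD at 12 hr, almost the same distance as from libraries B and C of a2NTD at 24 hr, 0.619. The library labelled a2NTD 12 hr A lay 1.56 from the other 2 of its group and 0.558 from the other 2 of a2NTD at 2 hr, its nearest group. The labels were kept as given in every comparison, and the number of wells past the threshold in each comparison is also given without these 2 libraries, an alternative chosen after seeing the data.

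**Figure D1:**
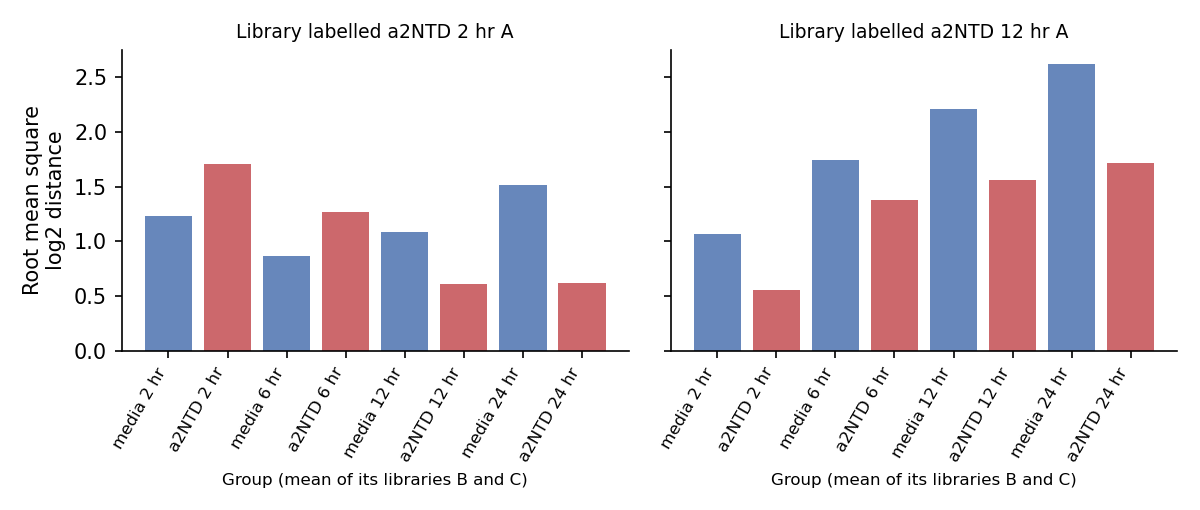
Root mean square log2 distance over 69 wells (y axis) from the library labelled a2NTD 2 hr A (left) and the library labelled a2NTD 12 hr A (right) to the mean of libraries B and C of each group (blue bars, media; red bars, a2NTD). The left library lay 1.71 from its own group, 0.609 from a2NTD at 12 hr and 0.619 from a2NTD at 24 hr, and the right library lay 1.56 from its own group and 0.558 from a2NTD at 2 hr.

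The comparison at 2 hr asked which transcripts responded to a2NTD early. No well of the 76 tested passed limma's adjusted p of 0.05, while 7 had an unadjusted p under 0.05. The smallest adjusted p belonged to well C6, chosen after its values were seen, at -3.16 ± 0.32 (SD, n = 3) in a2NTD and -4.67 ± 0.15 in media, a difference of 1.50 ± 0.39 (SE; adjusted p = 0.0846). Well B12, chosen likewise, had the second smallest p, with a difference of 2.78 ± 0.81 (SE; adjusted p = 0.101), and both wells were higher in a2NTD in 3 of 3 replicates. Without the libraries labelled a2NTD 2 hr A and a2NTD 12 hr A, 15 wells passed, 14 higher and 1 lower, among them C6 (3.22-fold, adjusted p = 0.00776), while B12 did not (adjusted p = 0.102). With a replicate block, of letters within times or of the 3 letters, 3 wells passed, all higher. Leaving out a2NTD 2 hr A alone gave 7 wells, so that the count of 0 at 2 hr depended on that library.

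At 6 hr, 13 of 79 wells were higher in a2NTD and none was lower. Well B7 rose from -9.21 ± 0.64 in media to -5.34 ± 1.62 in a2NTD (SD, n = 3), which is 14.7-fold (95% interval 4.37 to 49.1; adjusted p = 0.00277). Well B12 rose 14.5-fold (4.50 to 46.7; adjusted p = 0.00254), from -13.09 ± 0.90 to -9.23 ± 0.55. Both were higher in a2NTD in 3 of 3 replicates. With replicates paired by letter within each time as a replicate block, 21 wells passed, all higher, and without the 2 libraries that stood apart 21 wells also passed. Without replicate B at all times no well passed, with 2 libraries left per group, while B7 was then 17.4-fold higher (adjusted p = 0.0790) and B12 11.8-fold (adjusted p = 0.0988). A Ct ceiling of 40 also ended the call of B12 (adjusted p = 0.0837), at an unchanged 14.5-fold.

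At 12 hr, 15 of 77 wells were higher in a2NTD and 1 was lower. Well B12 showed the largest rise, 33.4-fold (95% interval 10.4 to 107.7; adjusted p = 0.000381), from -14.69 ± 1.49 to -9.63 ± 0.80 (SD, n = 3). Well B4 rose 21.96-fold (5.28 to 91.4; adjusted p = 0.00328), from -7.90 ± 0.45 to -3.44 ± 2.09, and its large SD came with the library labelled a2NTD 12 hr A, without which, and without a2NTD 2 hr A, the rise was 9.54-fold (adjusted p = 0.000117). Well G5 was lower by -1.77 ± 0.62 (SE; adjusted p = 0.0486), from -14.05 ± 0.58 in media to -15.82 ± 0.13 in a2NTD, at a mean Ct of 33.2 in a2NTD, near the ceiling of 35. That call was lost when any 1 of the 6 libraries of this time was left out, where the difference lay between -1.44 and -1.98. Without the 2 libraries that stood apart, 15 wells passed, all higher, and without a2NTD 12 hr B 26 wells passed. Without the plates on which H6 read under 35, 5 wells passed. Those plates leave 1 library per group at this time, and B12 was then 7.42-fold higher (adjusted p = 0.104).

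At 24 hr, 15 of 79 wells were higher in a2NTD and none was lower. Well C12 rose at least 25.1-fold (adjusted p = 0.000277), from -16.82 ± 1.11 in media to -12.17 ± 1.07 in a2NTD (SD, n = 3). The Ct of C12 was over the ceiling in 2 of the 3 media libraries and set to 35, so that this fold is a lower bound. Well B12 rose at least 24.8-fold (adjusted p = 0.000277), from -15.92 ± 1.52 to -11.29 ± 0.80, and 1 of its 3 media readings was undetermined and set to 35. Both wells were higher in 3 of 3 replicates. Without the 2 libraries that stood apart 21 wells passed, all higher, and without a2NTD 24 hr C 9 wells passed. Leaving out all of replicate B gave 6 wells and all of replicate C 7, and leaving out the plates on which H6 read under 35 gave 6.

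**Figure D2:**
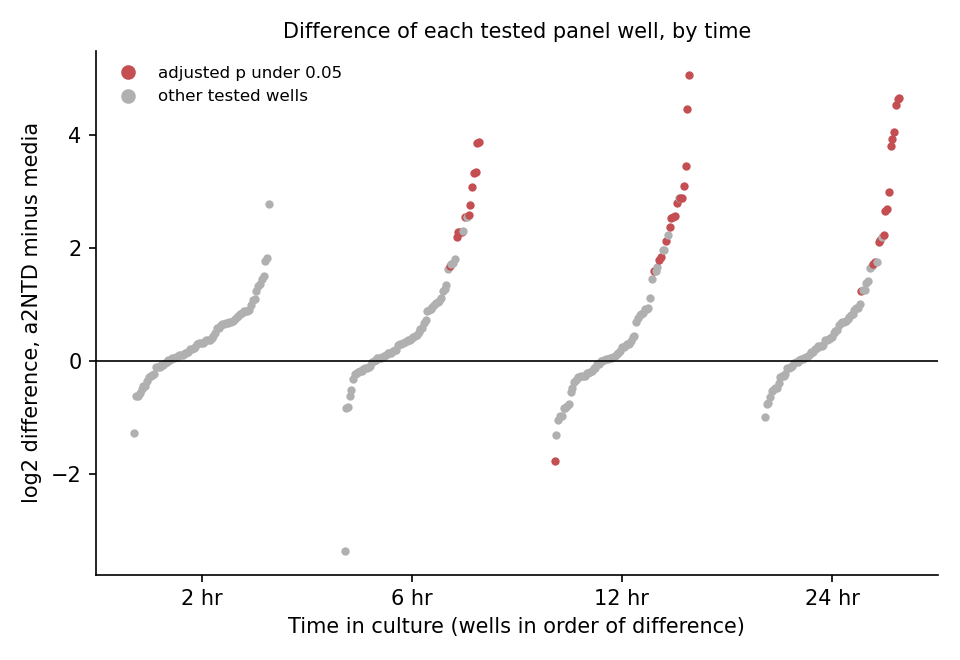
log2 difference between a2NTD and media (y axis, difference of group means, n = 3 per group) of each panel well tested at 2, 6, 12 and 24 hr (x axis), with wells ordered by their difference within each time and wells past limma's adjusted p of 0.05 in red. There were 0, 13, 16 and 15 such wells at the 4 times, and all but 1 of them, G5 at 12 hr, were higher in a2NTD.

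The wells that rose were largely shared between times. Of the 13 wells that rose at 6 hr and the 15 that rose at 12 hr, 12 were shared, against 2.57 from independent lists of those sizes among the 76 wells tested at both. The 6 and 24 hr lists shared 13 wells, against 2.53, and the 12 and 24 hr lists shared 13, against 2.96. The means of different times share no library, but the model shares 1 estimate of each well's spread and so favours the same wells at every time. With a separate fit per time the lists shared 12 wells, 16 and 12 in the same order, against 3, 4.94 and 3.16, and without the 2 libraries that stood apart 14, 15 and 14, against 4.14, 5.73 and 4.14. With the panel's median Ct as reference they shared 3, 5 and 6, against 0.526, 0.649 and 1.05, with the median deviation 6, 6 and 10, against 1.11, 0.857 and 2.03, and with no reference 13, 11 and 12, against 3.93, 2.03 and 3.63. In all, 12 wells rose at each of 6, 12 and 24 hr and 17 rose at 1 or more of these times. The median difference of those 12 wells was 2.57 at 6 hr, 2.67 at 12 hr and 2.84 at 24 hr, and at 2 hr, where none of them passed, it was 1.28, with all 12 above 0. Leaving out the 2 libraries that stood apart, 13 wells rose at each of 6, 12 and 24 hr, and 7 of these also at 2 hr.

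**Figure D3:**
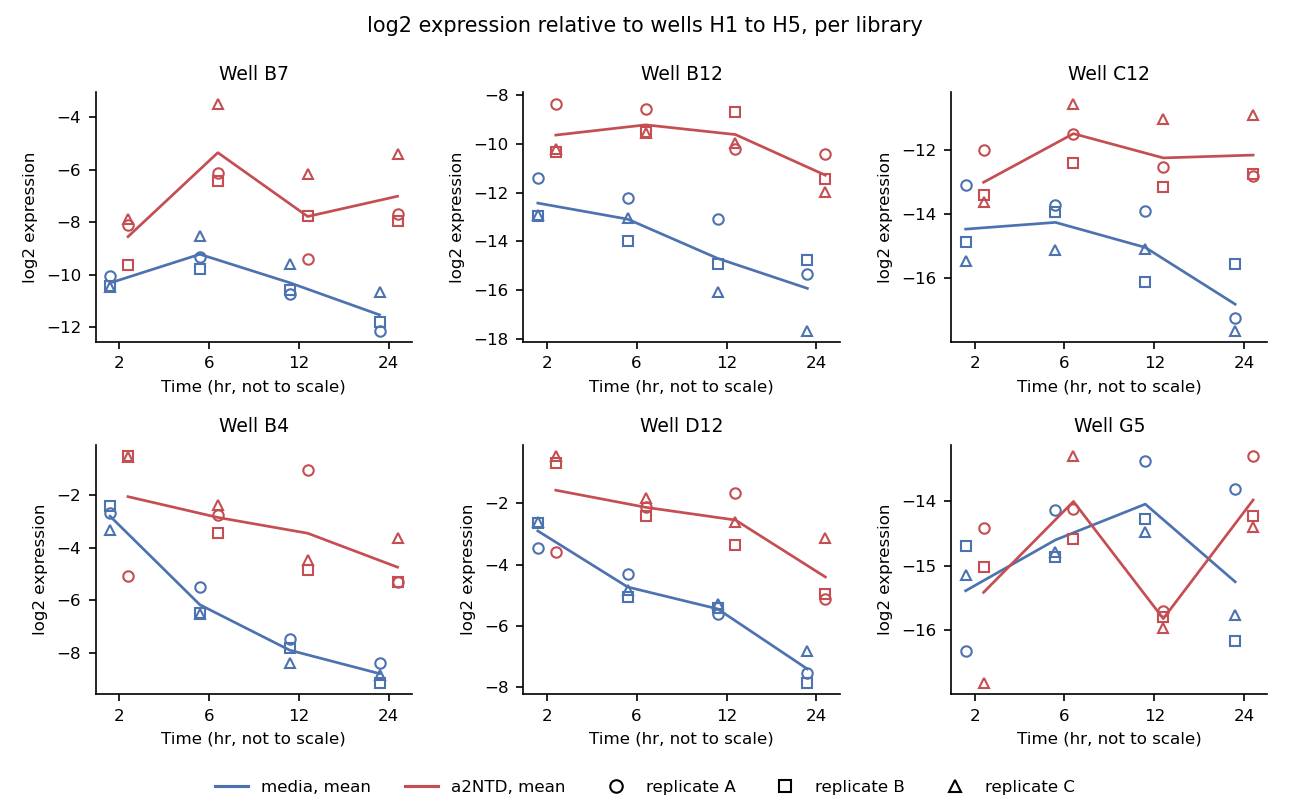
log2 expression relative to wells H1 to H5 (y axis) of 6 wells named in the text at 2, 6, 12 and 24 hr (x axis), with 1 symbol per library (circles, replicate A; squares, B; triangles, C) and lines through the means of media (blue) and a2NTD (red). In B4 and D12 the red circles at 2 and 12 hr, the libraries that stood apart, lie away from the other red symbols of their times, and the media means of both wells fall from 2 to 24 hr.

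Averaged over the 4 times, 30 of 76 wells were higher in a2NTD and 1 was lower, and 20 of the 30 were higher by at least 2-fold. Well B12 was at least 17.0-fold higher (adjusted p = 3.20e-07), a lower bound because of its undetermined reading in media at 24 hr, and well B7 9.01-fold (95% interval 4.92 to 16.5; adjusted p = 4.96e-06). Well E12 was lower by -1.03 ± 0.37 (SE; adjusted p = 0.0311), at a mean Ct of 33.2 in a2NTD with 2 readings over the ceiling set to 35, and its call was lost in 17 of 52 alternatives, among them leaving out any 1 of 10 libraries (media 2 hr A or C, 6 hr C, 12 hr A and 24 hr A, and a2NTD 2 hr B, 6 hr A, 12 hr A or C and 24 hr C), where its difference lay between -0.78 and -1.01. Without the 2 libraries that stood apart, 36 wells passed, 33 higher and 3 lower. Of the 36, 22 differed by at least 2-fold in either direction, among them E12, which was lower by -1.09.

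The split between higher and lower wells depended on the scaling. With the panel's median Ct as reference in place of H1 to H5, the wells past the threshold were 5 higher and 3 lower at 6 hr, 8 and 26 at 12 hr, 10 and 20 at 24 hr, and 14 and 44 on average. That reference moved the median difference over wells by -0.66, -0.95, -0.92, -1.05 and -0.89 log2 units at 2, 6, 12 and 24 hr and on average. Centring each library on the median of its wells' deviations, an alternative chosen after seeing the data, moved the average by -0.31 and gave 22 higher and 8 lower. With no reference the average moved by 0.10 and gave 33 higher and 0 lower. By time, no reference gave 3 higher at 2 hr, 13 at 6 hr, 23 at 12 hr and 12 at 24 hr, with 0 lower at each.

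Plates of 1 letter were run together within a few days per the file headers, so that letters also mark PCR batches. With the 3 letters as a block, 3, 17, 17 and 17 wells passed at 2, 6, 12 and 24 hr. Within letters A, B and C, a2NTD exceeded media in 60.5, 72.4 and 57.9% of the tested wells at 2 hr, in 82.3, 84.8 and 70.9% at 6 hr, in 55.8, 62.3 and 64.9% at 12 hr and in 63.3, 79.7 and 72.2% at 24 hr. These shares are relative to H1 to H5. Over the group means the share at 2, 6, 12 and 24 hr was 75, 77.2, 63.6 and 74.7%, and it turned to 35.5, 35.4, 33.8 and 29.1% with the panel's median Ct. With the median deviation it was 63.2, 44.3, 50.6 and 55.7%, and with no reference 84.2, 79.7, 77.9 and 67.1%.

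Whether the response differed between times was tested as the interaction of treatment and time. No well of 76 passed in limma's F test, and 3 had an unadjusted p under 0.05. Without the 2 libraries that stood apart 1 well passed (adjusted p = 0.0270). This was C11, chosen after its values were seen, whose differences were then 0.11 ± 0.36 (SE) at 2 hr, 2.28 ± 0.32 at 6 hr, 2.74 ± 0.36 at 12 hr and 1.72 ± 0.32 at 24 hr.

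The media cultures alone also changed between times. Of 76 wells, 31 passed the F test over the 4 times (40 without the 2 libraries that stood apart, which share the estimate of the spread), of which 23 were lower and 8 higher at 24 than at 2 hr by estimate. That split also depended on the scaling, with 10 lower and 14 higher for the panel's median Ct, 18 and 12 for the median deviation and 16 and 4 for no reference. These scalings moved the median difference between 24 and 2 hr over wells by 0.91, 0.31 and 0.27 log2 units. Well D12 went from -2.91 ± 0.48 at 2 hr to -7.40 ± 0.53 at 24 hr (SD, n = 3), 22.5-fold lower (adjusted p of the F test 0.000933), and well E11 from -2.04 ± 0.32 to -5.03 ± 0.59, 7.95-fold lower (0.000933). Well F4 went from -14.57 ± 1.23 to -12.02 ± 0.20, 5.87-fold higher (0.00679), and well D1 from -5.89 ± 0.40 to -3.65 ± 0.35, 4.73-fold higher (0.0107). Leaving out 1 media library gave 15 wells without media 2 hr A, where D1 lost its call at a difference of 2.02, 14 without media 2 hr B and 19 without media 24 hr B. Without replicate B at all times no well passed, with differences of -4.13 in D12, -2.70 in E11, 2.37 in F4 and 2.48 in D1. Leaving out replicate C gave 5 wells and ended the calls of F4 (1.96) and D1 (2.18). Without the 8 plates on which H6 read under 35, among them 4 media plates of 12 and 24 hr, no well passed either, with differences of -4.64, -2.60, 2.32 and 2.14 in D12, E11, F4 and D1.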

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

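The tests of wells H8 and H9, of the 2 libraries that stood apart and of the predominance of rises were chosen after the results were seen. The counts of other splits of the samples were required from the start, with their bounds written down afterwards.

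Wells H8 and H9 lie outside the 84 wells taken as the panel and showed a signal in data that the comparisons do not use. What these wells hold is not known, and H1 to H5 were taken as reference wells from the same assumed layout of row H. H8 was higher in a2NTD by 1.31 ± 0.36 (SE) averaged over the times (adjusted p = 0.00742), at a mean Ct of 33.6 in media and 32.03 in a2NTD. H9 was higher by 0.98 ± 0.36 (adjusted p = 0.0341), at 22.04 and 20.97, and by time it passed at 24 hr (2.20, adjusted p = 0.0379). Without the 2 libraries that stood apart the difference in H9 went from 0.91 to -0.02 at 2 hr and from 0.19 to 1.15 at 12 hr.

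The libraries labelled a2NTD 2 hr A and a2NTD 12 hr A were each nearer to the other 2 libraries of the other's time than to those of their own. The sum of the 2 distances with their labels exchanged was 0.357 of the sum as labelled. Exchanges between times were computed for all libraries with the same letter and treatment, 36 in all. Ordinary spread between replicates is argued against by the size of this ratio, since the lowest of the others was 0.969. The pair was chosen because it stood apart, so that its rank as the lowest of 36 says nothing by itself. A failed plate would move a library away from all groups, but the larger of the 2 distances to the exchanged time was 0.609, under the median of 0.714 that other libraries lay from their own group. Low template is partly removed by the reference, but the mean Ct of H1 to H5 was 17.7 and 17.6, within the 16.9 to 18.1 of the other 22 plates. Well H12 of a2NTD 12 hr A, at a Ct of 16.7, lay above the highest of those plates, 16.5. An exchange of the 2 libraries is a candidate explanation, although the file headers name the treatment and time of the labels and the library labelled a2NTD 2 hr A lay nearly as close to libraries B and C of a2NTD at 24 hr (0.619). A different course in the cultures of that occasion stays open and untested.

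Of the wells that changed on average, 30 were higher and 1 was lower. Reference wells moving between treatments are argued against for the average, since 30 of the 30 remained higher with no reference. By time the reference mattered more, with 15 higher wells at 12 hr becoming 23 and 15 at 24 hr becoming 12 with no reference. Another PCR product is argued against too, since 0 of the 30 had median melting temperatures over 1 °C apart between treatments (largest difference 0.65 °C). A shift common to the whole panel stays open as a cause of the predominance. Of the 30 wells, 22 remained higher after each library was centred on the panel's median deviation, with 8 wells lower, and 14 with the panel's median Ct as reference, with 44 lower. The same 14 wells remained higher under both. A response to a2NTD is the biological explanation that the design names. Media alone was the only other condition, so that this means a response to the a2NTD preparation as added. As causes of the predominance, a common shift and such a response cannot be told apart, because the scalings differ on it and no well is known to be unaffected by a2NTD.

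With 6 libraries per time there are 10 splits, too few for a share under 0.05. The labelled split gave 0 wells at 2 hr against at most 2 in another, 13 at 6 hr against 1, 16 at 12 hr against 0 and 15 at 24 hr against 1, so that 1 split at each later time gave as many. A count of 0 is matched by every split, so the 10 of 10 at 2 hr say nothing about chance. For the average, 1 of 100 splits within times gave as many as 31 wells, the labelled one, with 19 the highest of the others, and for the media time course 1 of 100 gave as many as 31, with 9 the highest of the others. Chance is argued against for both if libraries are freely exchangeable, and 1 of 100 is the smallest share these draws can give. The splits ignored the letters, which were taken to pair libraries at 6, 12 and 24 hr. No split that keeps letters together was run. For the interaction, with 0 wells, the 100 of 100 permutations of residuals that gave as many say nothing about chance for the same reason, and some gave up to 5.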

How the results depend on the processing

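Chosen after seeing the data were leaving out the 2 libraries that stood apart, references of 4 wells, centring on the median deviation, testing row H and matching melting temperatures. The cause of a change was not tested unless stated.

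The count of 31 wells on average over times stayed within 1.5 times in 52 of 54 alternatives, and the wells named as higher in a2NTD kept their direction in all of theirs. That count ignores direction, so that the median deviation, with 22 higher and 8 lower, is among the 52. Over the counts of all comparisons, 266 of the alternatives' values stayed and 40 moved. Over the named wells, 528 of the alternatives' values kept direction and side of the threshold, 55 kept the direction and lost the call, and none reversed. G5 at 12 hr lost its call in 23 of 36 (adjusted p 0.00999 to 0.174) and E12 on average in 17 of 52 (0.000312 to 0.248), while B12 at 6 hr (3.37e-05 to 0.0988) lost it in 2 of 37, B12 at 12 hr (6.32e-06 to 0.104) in 1 of 37 and B7 at 6 hr (2.05e-05 to 0.0790) in 1 of 37. In the media time course, of 42 alternatives each, D12 (5.10e-07 to 0.116) and E11 (1.44e-05 to 0.123) lost it in 2, F4 (0.000586 to 0.292) in 3 and D1 (9.68e-07 to 0.242) in 4.

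Leaving out a library or a letter gave 0 to 14 wells at 2 hr, 0 to 17 at 6 hr, 10 to 26 at 12 hr, 6 to 20 at 24 hr, 18 to 35 on average, 0 for the interaction and 0 to 28 for the media time course. The ends were a2NTD 12 hr B for 26, replicate A for 14, 17, 20 and, with replicate C, 10, and replicate B for 6, 18 and 0 at 6 hr and in media, where 2 libraries per group remain. Leaving out both libraries that stood apart gave 15 wells at 2 hr, 21 at 6 hr and 1 for the interaction (from 0, 13 and 0), and with the 3 letters as a block as well 20, 29 and 30 wells at 2, 6 and 24 hr, 6 for the interaction and 50 for the media time course.

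The replicate block of letters within times gave 3 wells at 2 hr, where the letters were not taken to pair libraries, and 21 at 6 hr, and changed no other count by over 1.5 times and no call of a named well. The block of 3 letters gave 3 at 2 hr. Of 12 media libraries, 10 correlated best with the a2NTD library of their own letter.

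The panel's median Ct as reference gave 8 wells at 6 hr, 34 at 12 hr, 30 at 24 hr and 58 on average. This median tracks the wells of middle abundance, whose median difference between treatments was 0.89, against 0.22 over all wells. Centring on the median deviation gave 7 at 6 hr. Raw Ct gave 3 at 2 hr and 20 for the media time course. At 2 hr, H4 alone gave 1 well, a ceiling of 32 gave 2, and an adjusted p under 0.1 gave 1. Leaving out the 8 plates with H6 under 35 gave 5 wells at 12 hr, 6 at 24 hr and 0 for the media time course, where a2NTD at 12 hr and media at 12 and 24 hr keep 1 library each, assumed to vary like the other groups. Not run were the reference without B2M and those by gene name, for which wells H1 to H5 were used singly, the gene lists and the limit on reverse transcription controls. Wells within a few cycles of the ceiling limit what could be called lower.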

Other observations

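The tests in this part were chosen after the results were seen.

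Wells that fell with time in media overlapped those that rose with a2NTD. Relative to H1 to H5, between 2 and 24 hr in media, 22 wells fell and 5 rose past an adjusted p of 0.05. Of the 13 wells that rose in a2NTD at 6 hr, a comparison whose means share no library with that fall but whose estimate of the spread is shared, 11 were among the wells that fell in media, against 3.76 from independent lists among 76 wells, and 0 were among those that rose. With a fit of each comparison's own 6 libraries, 18 of 19 were shared, against 6.25, and without the 2 libraries that stood apart 17 of 21, against 6.63. The split of falls and rises depended on the scaling, with 15 and 24 for the panel's median Ct, 21 and 10 for the median deviation and 22 and 6 for no reference. The shared wells were then 3 of 5, against 0.987, 5 of 6, against 1.66, and 11 of 13, against 3.76. Relative to H1 to H5, well B4 had the largest fall, from -2.79 ± 0.47 at 2 hr to -8.79 ± 0.37 at 24 hr (SD, n = 3), 64.1-fold.

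A slower fall from the level at 2 hr in media as the whole cause is a hypothesis for the wells higher in a2NTD at 24 hr, all 15 of which were lower in media at 24 than at 2 hr by estimate. That count is favoured by their selection, since the same media libraries of 24 hr enter both differences. A slower fall is argued against as the whole cause by the level at 6 hr for 6 of the wells, except C11 among them. The means at 6 hr took no part in choosing these wells, but those libraries entered the shared estimate of each well's spread. In a2NTD at 6 hr, 10 of the 15 lay above the media level at 2 hr past the threshold adjusted over these wells, by 1.16 to 4.97 (SE 0.39 to 0.83). With the panel's median Ct or the median deviation 6 of the 15 did, and the same 6 did so under every scaling and without the 2 libraries that stood apart. In media, 1 of these 6, C11, also rose past the threshold from 2 to 6 hr, by 1.80, and 4 of the 15 fell. The level at 2 hr is thus not the one from which C11 fell in media, and for C11 a slower fall stays open. For the other 9 wells a slower fall stays open. Their level at 6 hr depends on the scaling, has too large an SE, or was not above the media level at 2 hr by estimate. The last holds relative to H1 to H5 for B4 (-0.05 ± 0.98, SE) and C8 (-0.13 ± 0.69). In a2NTD at 2 hr, all 15 wells lay above the media level at 2 hr by estimate, and 2 past the threshold. Without the 2 libraries that stood apart 9 did so past the threshold, with the panel's median Ct 0 and with the median deviation 1. The level at 2 hr thus depends on those libraries and on the scaling, and does not decide the question. At 24 hr, 8 of the 15 lay above the media level at 2 hr by estimate, and 1 past the threshold, B7 (3.31 ± 0.83, SE; adjusted p = 0.0124). Leaving out the 2 libraries that stood apart, 4 lay above it and 3 below it past the threshold at 24 hr. A rise followed by a slower fall was not tested. No library from before the stimulation was analysed here, so that the level from which the media cultures fell is not known.

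The share of wells that rose on average is given here by abundance. Of 27 wells with a mean media Ct of 24 to 28, 13 rose and the median difference was 0.89, while of 30 wells under 24, 11 rose with a median of 0.20, and of 19 over 28, 6 rose and 1 fell with a median of 0.06. Leaving out the 2 libraries that stood apart, 14, 12 and 7 rose, with medians of 0.81, 0.21 and 0.20. The differences between these classes were not tested.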
